A study of Mus musculus with 2 samples.

How the data were processed

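ChIP-seq was carried out on αTC1-9 cells expressing Glis3 fused to FLAG and mCherry, with a FLAG affinity gel, and 1 input library was sequenced beside it. Per the labels' protocols, chromatin was cross-linked with formaldehyde and sonicated, and size-selected DNA was made into Illumina libraries. Bowtie and the mm9 genome build are named in the submitters' processing notes; the Bowtie version and settings are not given in the sources used here.

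The deposited table lists binding sites called with SISSRs 1.4, per the file header, which finds places where tags on the sense strand give way to tags on the antisense strand. The header gives an E-value of 10, a p-value threshold of 0.0001, a scanning window of 20 bp, a mean fragment length of 210 bp, a mappable fraction of 0.80 of the genome, 1 tag kept per position, and at least 2 directional tags on each side of a site. It states 17 tags and an 18.00-fold enrichment as the limits for a site. The authors called sites on 1 ChIP library against 1 input library, with no pooling recorded. The table holds, as deposited, a count of ChIP tags per site, a fold of ChIP over input, and a p-value from the caller for each site. The fold and p are the caller's own values and were used only to describe, rank or filter sites within this list.

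The labels and files disagree on the sample in places. Both tag file names that the header records hold the word Liver, whereas the labels name αTC1-9 cells, and the ChIP step of the labels' protocol speaks of ES cells. The sample is described here as labelled, and every result holds for the library behind the deposited list.

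The analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Positions are printed as deposited, in mm9; whether they count from 0 or 1 is not given in the sources used here. Distances were taken between interval centres. The implied input of a site was computed as tags × (input total / selected ChIP total) / fold and called whole within 0.01. Intervals of counts are exact 95% Poisson intervals, those of shares exact Clopper-Pearson intervals, and those of folds follow from the exact binomial interval of the ChIP share of the tags; all cover counting error only.

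The naming rule, the tests of spacing, of neighbouring pairs and of tags against fold, and part of the alternatives were fixed before the data were examined. The rule names the 10 sites of highest fold (ties by tags, then position) and the 10 with the most tags, and genes near sites only with an mm9 annotation, so sites are named by position. The plan gave counts per chromosome without a test where no mm9 genome was given. The tests against the span from first to last site, multiplied by (n + 1)/(n - 1) for n sites, and against gene number (protein-coding genes of the GRCm38.p6 RefSeq table) were chosen after the counts had been seen, as were the input counts, the test of the densest 1 Mb window and the alternatives listed as such in the closing section. Chromosome counts were tested by a Monte Carlo multinomial test of the chi-square statistic (10000 sets) and by two-sided exact binomial tests with Benjamini-Hochberg adjustment at 0.05. Spacing was compared with 10000 sets of random positions, pairs of neighbours with 10000 sets of random pairs, and the rank correlation across chromosomes with 100000 permutations. No test between libraries was possible with 1 library of each kind.

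The tests were tried on simulated data. The spacing test called 2 of 50 sets of uniform sites and 50 of 50 sets in which 1 site in 10 was moved to within 50 kb of another. The chromosome test found 150 of 150 chromosomes raised 3-fold and made any call in 3 of 50 sets with none raised. Those sets held independent sites and took the span as known. They therefore do not give the error rate for sites that lie close together or for a span estimated from the sites. Simulated input counts were recovered at 1343 of 1343 sites. This checks only the rounding, since the same formula made the folds and was then inverted. The simulation held no case like the 85 sites whose implied input was not whole. The test of neighbouring pairs called 4 of 50 sets with shuffled folds. The rank correlation called 2 of 50 unrelated sets of 20 values. The test of the densest window called 0 of 50 sets of uniform sites and 50 of 50 sets with 15 sites moved into 1 window.

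Planned comparisons with transcription start sites, annotation classes, Glis3 motifs, new motifs, repeats, gene lists and the insulin promoters were not run, because each needs mm9 sequence or annotation and positions were not converted between builds.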

Results

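Binding of Glis3, a Krüppel-like zinc finger transcription factor known as an activator of insulin gene transcription, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in αTC1-9, a mouse cell line with the character of pancreatic α cells, which normally make glucagon. The cells expressed Glis3 fused to FLAG and mCherry, and the anti-FLAG precipitate was compared with input chromatin of the same line. There was 1 ChIP library and 1 input library. Per the file header, the ChIP library held 20037091 tags (mapped read positions), of which 19551047 (97.57%) were used, and the input held 18603239. The series asked where in the genome Glis3 is bound, which sequence it prefers and whether it occupies the insulin promoter. The site list bears on the first question: it gives places enriched in the FLAG precipitate over input, by position in the mm9 genome. No FLAG precipitate of cells without the fusion was among the samples. Background of the FLAG gel therefore cannot be told from Glis3 binding. Distances to the insulin promoters and to other genes, and sequence motifs, were not analysed here, because no mm9 sequence or annotation was used. With single libraries there is no replicate error: the intervals below cover counting error only, and the permutation tests compare the sites with random placement, not one condition with another.

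The list held 1343 sites, on chromosomes 1 to 19 and X. A site had a median of 24 ChIP tags (quartiles 20.5 and 32, range 19 to 94) and a median fold over input of 21.9 (quartiles 19.03 and 27.6, range 18.1 to 89.4). The calling limit was 18.00-fold. Of all sites, 615 (45.8%) had at least 25 tags, 222 (16.5%) at least 38, 83 (6.2%) at least 50 and 9 (0.7%) at least 75. The caller's p-values ran from values listed as 0, at 3 sites, to 8.7e-05, and 176 sites had a p of at most 1e-05. The called intervals were short, with a median of 60 bp and a maximum of 580 bp. Intervals of 40 bp made up 446 sites (33.2%) and intervals of 60 bp a further 288 (21.4%).

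The highest fold, 89.4, was shared by 3 sites with 94 tags each (95% exact Poisson interval 76.0 to 115). They lay on chromosome 2 at 172866971 to 172867011, on chromosome 11 at 32095291 to 32095391 and on chromosome 11 at 118990171 to 118990231 (mm9 positions as deposited). The site next in rank, on chromosome 5 at 28071451 to 28071811, had 89 tags and a fold of 84.7, and its nearest other site was 532 kb away. It was followed by a site on chromosome 11 at 98790111 to 98790211 (80 tags, 76.1-fold), one on chromosome 17 at 25410631 to 25410731 (77 tags, 73.3-fold) and one on chromosome 1 at 95107931 to 95108011 (74 tags, 70.4-fold). The site on chromosome 1 had another called site 930 bp away. The 10 sites of highest fold were completed by sites with 71 or 72 tags: on chromosome 2 at 163264051 to 163264271 (68.5-fold), on chromosome 9 at 62540891 to 62540931 (68.5-fold) and on chromosome 7 at 105719311 to 105719511 (67.6-fold). At each of these 10 sites the fold matched an input of 1 tag, which may have been 1 tag or none raised to 1 by the caller. Taken as 1 tag, it gave the fold at the chromosome 5 site an exact interval of 14.8 to 3382, so the order of the 10 sites by fold was not resolved.

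Ranking by tags in place of fold kept 7 of the 10 sites. The other 3 were sites with a higher input count. A site on chromosome 11 at 98993711 to 98993771 had 93 tags over 3 input tags (29.5-fold, exact interval 9.79 to 146). A site on chromosome 11 at 95043371 to 95043431 had 83 tags over 3 input tags (26.3-fold, 8.70 to 130). A site on chromosome 15 at 73763591 to 73763651 had 76 tags over 4 input tags (18.1-fold, 6.78 to 68.1). Of the 13 sites named by either ranking, 5 were on chromosome 11 and 2 on chromosome 2.

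**Figure D1:**
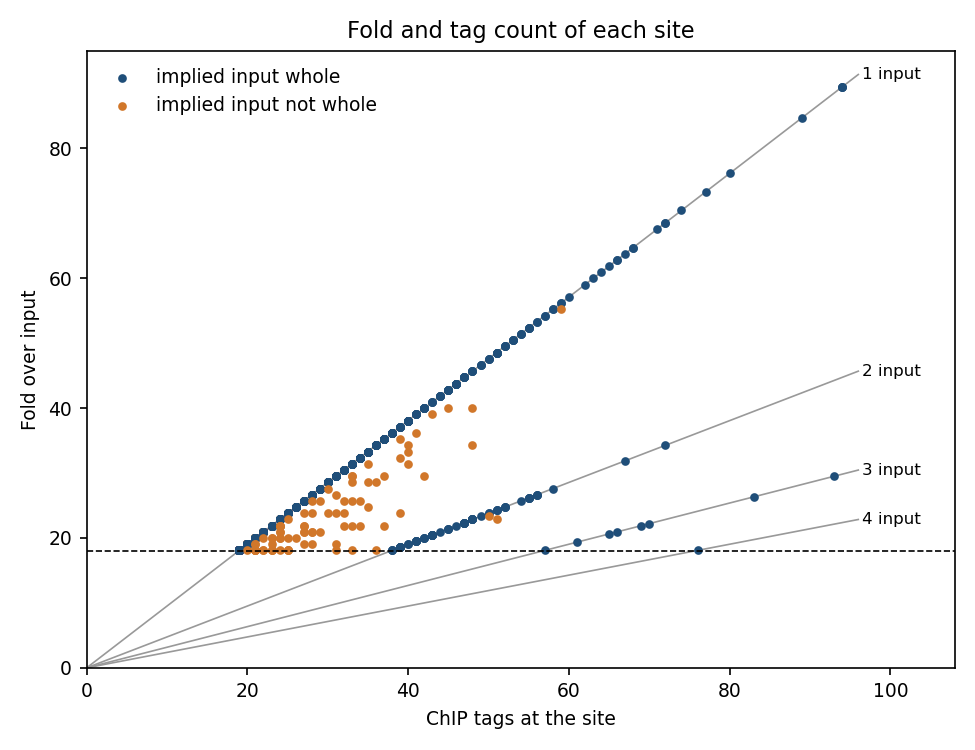
Fold over input (vertical axis) against the number of ChIP tags (horizontal axis) for each of the 1343 sites. Grey lines show the fold expected for 1 to 4 input tags from the library totals, the dashed line is the 18.00-fold limit, and 1183 sites lie on the line for 1 input tag.

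Spearman's rho between tags and fold was 0.88 across the sites, a relation that is built in, because the caller computes the fold from the tags. Multiplying the tags by the ratio of the library totals (0.9515) and dividing by the fold gave an implied input for each site. It was 1 within 0.01 at 1183 of 1343 sites (88.1%, exact 95% interval 86.2 to 89.8), 2 at 66 sites, 3 at 8 sites and 4 at 1 site. At the other 85 sites it lay between 1.02 and 2.13 and was not whole, so that it is no input count there. At 84 of these 85 the fold divided by the ratio of totals was whole within 0.01, as it would be for an input of 1 and fewer tags than the number listed. For an input of 1, 19 tags were needed to reach 18.00-fold, and for an input of 2, 38 tags, so that below 38 tags no site with an input of 2 or more could be called. Among the 222 sites with at least 38 tags, 132 (59.5%, 52.7 to 66.0) had an input of 1 and 66 (29.7%, 23.8 to 36.2) an input of 2. Whether a value of 1 stands for 1 input tag or for none raised to 1 by the caller could not be told from the file.

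Sites were unevenly divided between chromosomes. Chromosome 11 held 149 sites (11.1% of the list), chromosome 2 held 142 and chromosome 1 held 124, whereas chromosomes 3 and X held 10 each and chromosome 14 held 16. Relative to the span between the first and last site of each chromosome, corrected for its ends, chromosome 11 had 1.27 sites per Mb (exact Poisson interval 1.08 to 1.49), chromosome 17 had 0.902 (0.721 to 1.12), chromosome 15 had 0.878 (0.704 to 1.08) and chromosome 2 had 0.785 (0.662 to 0.926). Chromosome X had 0.0560 (0.0269 to 0.103), chromosome 3 had 0.0811 (0.0389 to 0.149), chromosome 14 had 0.132 (0.0754 to 0.214) and chromosome 9 had 0.263 (0.180 to 0.371). The numbers differed from those expected by span (chi-square = 388, permutation p = 0.0001, the smallest that 10000 random sets can give; highest chi-square of the random sets, 47.3). By exact binomial tests with Benjamini-Hochberg adjustment over the 20 chromosomes, 5 held more sites than expected (1, 2, 11, 15 and 17) and 5 fewer (3, 9, 13, 14 and X). Chromosome 11 had 2.40 times the expected number (exact binomial test, adjusted p = 5.45e-21) and chromosome X 0.106 times (adjusted p = 3.39e-28). The span can err either way where sites are few. Its correction assumes sites spread evenly, which the spacing below goes against, and chromosome lengths were not used. The last site on chromosome 3 was at 110 Mb, and the end correction raised the span of chromosome X from 146 to 178.5 Mb; without the correction chromosome X had 0.0685 sites per Mb and chromosome 1 no longer passed as higher.

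A similar division was seen when sites were set against the number of protein-coding genes assigned to each chromosome in the RefSeq table of GRCm38.p6, used for gene numbers and not for positions (chi-square = 279.8, permutation p = 0.0001, the smallest possible). Chromosome 15 had 11.3 sites per 100 genes (9.10 to 13.97), chromosome 1 had 10.3 (8.57 to 12.3) and chromosome 11 had 9.26 (7.83 to 10.9). Chromosome 3 had 1.02 (0.488 to 1.87), chromosome X had 1.04 (0.496 to 1.90) and chromosome 14 had 1.88 (1.08 to 3.06). Chromosomes 1, 2, 11, 15 and 17 were again higher and chromosomes 3, 9, 14 and X again lower by the adjusted binomial test. Chromosome 12 passed as higher against gene number (exact binomial test, adjusted p = 0.00725) and not against span (0.982 times the expected number), chromosomes 7 and 19 passed as lower against gene number alone, and chromosome 13 passed as lower against span alone. The chi-square and binomial tests both treat sites as independent, and the chi-square test was not repeated with nearby sites merged. Against span, chromosomes 1 and 13 no longer passed with sites within 100 kb counted as 1 (8 chromosomes called), chromosome 2 no longer passed with the 711 sites at or above the median fold (9 called), and with the 176 sites of p at most 1e-05 only chromosomes 11 (higher) and 3, 14 and X (lower) passed. These settings were not run against gene number.

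**Figure D2:**
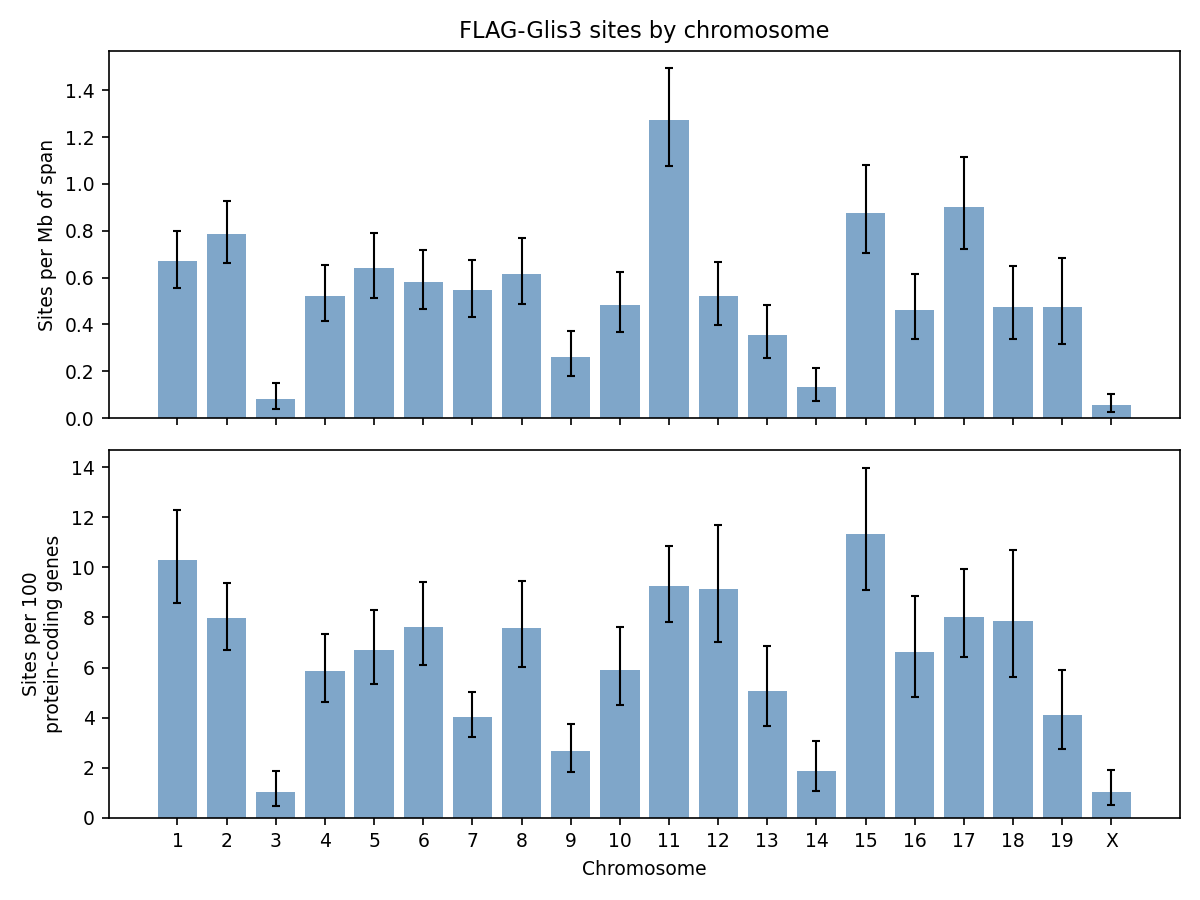
Sites per Mb of the span from first to last site (upper panel) and per 100 protein-coding genes (lower panel) for each chromosome; bars are the values and whiskers exact 95% Poisson intervals. Chromosomes 3, 14 and X are low in both panels, at 1.02, 1.88 and 1.04 sites per 100 genes.

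Sites lay close together along chromosomes. The median distance between neighbouring sites was 349 kb (quartiles 62.2 kb and 1505 kb), the smallest was 220 bp and the largest gap 42.9 Mb. Of the 1343 sites, 636 (47.4%) had another site within 100 kb, against a mean of 172 (12.8%, 95% range 140 to 204) for positions drawn at random between the first and last site of each chromosome (permutation p = 0.0002, two-sided, the smallest that 10000 sets can give). Within 10 kb the number was 253 against 18.4 at random, and within 1 kb it was 110 against 1.84 (permutation p = 0.0002 for each). Joining sites within 1 kb left 1284 regions, and joining those within 100 kb left 933, of which the largest held 10 sites. Random positions were drawn without regard to gene density or to how well reads map, which also vary along chromosomes.

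**Figure D3:**
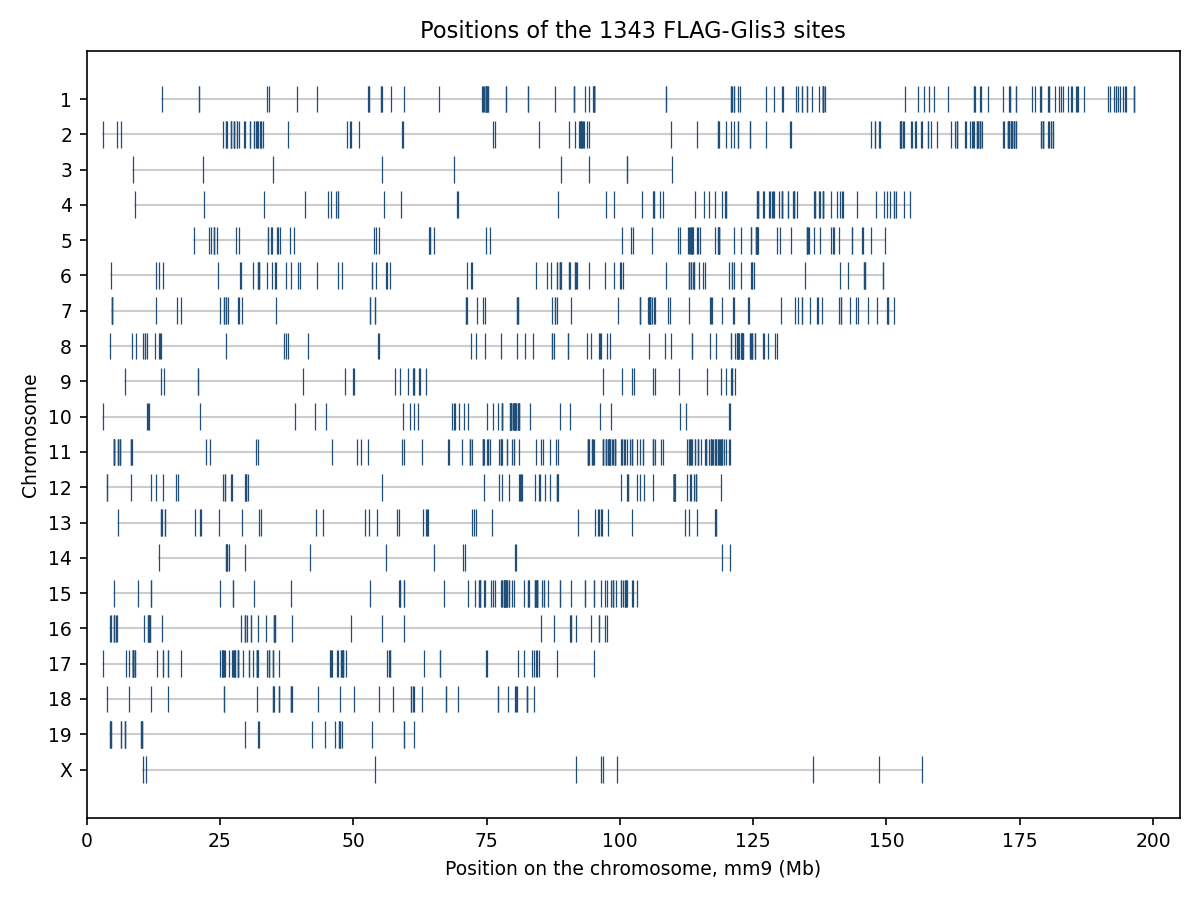
Position of each of the 1343 sites (vertical ticks) along the mm9 chromosomes; the horizontal axis is the position in Mb and grey lines join the first and last site of each chromosome. Chromosome 11 carries 149 ticks and chromosomes 3 and X carry 10 each. Spacing was tested over all chromosomes together, not for each chromosome.

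No greater likeness in strength was detected between sites called next to each other than between unrelated sites. Over the 59 pairs of neighbours within 1 kb, log2 fold differed by a mean of 0.47 ± 0.37 (SD over pairs), against 0.44 for random pairs of sites (95% range 0.34 to 0.54; permutation p = 0.52, two-sided). Over the 144 pairs within 10 kb the difference was 0.49 ± 0.39 against 0.44 (permutation p = 0.098). By tag count, the pairs within 1 kb differed by more than random pairs (0.66 ± 0.45 against 0.51, 95% range 0.40 to 0.62; permutation p = 0.0108, two-sided). Pairs within 1 kb can be separate calls within 1 region of enrichment.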

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

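The alternatives for chromosomes with gene number, with the span uncorrected, with merging at 100 kb, with stronger sites or without sparse chromosomes, those for spacing with sites within 1 kb merged, without the 5 densest windows or without sparse chromosomes, and all those for the densest window and the input counts, were chosen after seeing the data. Of 27 alternatives over 7 results, 19 kept the direction and side of the threshold, or stayed within 1.5 times of a count or within its interval. The alternatives limited to the numbered chromosomes and X, for the number of sites and for tags against fold, hold every site and could not differ. Those for tags against fold also rest on a relation that is built in. The number of sites fell from 1343 to 711 at or above the median fold, to 681 at or above the median tag count and to 176 at a p of at most 1e-05, by construction. The number of chromosomes that departed from their span fell from 10 to 4 with those 176 sites. It fell to 6 without the chromosomes with fewer than 20 sites (3, 14 and X), where chromosome 1 no longer passed. Neighbours within 1 kb differed from random pairs by 0.157 on the log2 scale when tags replaced fold, past the threshold, against 0.0323 for fold; the cause was not tested. The share of sites with an implied input of 1 fell from 88.1% to 59.5% among sites with at least 38 tags. It was 0.1% when all ChIP tags replaced the selected tags as the total, which shows that the caller scaled by the selected tags. Spacing kept its direction in each of its 6 alternatives, with 3.58 to 59.6 times the random number against 3.71; the permutation p was the smallest possible throughout and shows no more. Alternatives that need mm9 sequence or annotation were not run. No paired analysis was possible because there is 1 library of each kind. Depth limits the folds: an input count of 1 has an exact interval of 0.0253 to 5.57.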

Other observations

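The tests of the densest window, of span and gene number and of the input floor were chosen after the results were seen. The spacing tests with merged sites or without dense windows were added after the list had been examined, before their own results were seen. The site counts already implied the outcomes of these spacing tests, as given below. The densest stretches of up to 1 Mb held 17 sites each: one on chromosome 10 from 79364031 to 80320951 and one on chromosome 8 from 122027291 to 122949431. Random positions reached 10 at most (mean 6.10; permutation p = 0.0002, two-sided, the smallest possible). Next came stretches with 12 sites each on chromosome 1 from 74421891 to 75334591 and on chromosome 15 from 77867111 to 78765711. A stretch on chromosome 12 packed 10 sites into 216 kb, from 110074631 to 110290271. Sites there were of ordinary strength, with a median of 23.5 tags, as were those on chromosome 10 (median 23) and chromosome 8 (median 24). A stretch on chromosome 2 from 172764251 to 173616091 had 11 sites with a median of 32 tags and held one of the 3 sites of highest fold. Merging sites within 1 kb left the highest number at 17, and with sites at or above the median fold it was 12 (random maximum 8). These stretches are places to annotate first once the mm9 genes are at hand.

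Site numbers differed between chromosomes far more than the estimated span or gene number would give. Chromosome lengths themselves were not used. Density per Mb of end-corrected span differed 22.7-fold between chromosomes 11 and X (1.29 and 0.0685 sites per Mb without the correction). Sites per gene differed 11.2-fold between chromosomes 15 and 3, and density after counting sites within 100 kb as 1 still 13.6-fold. In each case the intervals did not overlap, though those per Mb take the span, itself estimated from the sites, as known. These differences argue against the estimated span, gene number or repeated calls as the whole cause. A candidate explanation is unequal copy number of chromosomes. It predicted before the test that chromosomes with more sites per gene have more tags per site. Spearman's rho was 0.66 over 20 chromosomes (permutation p = 0.0021) and Pearson's r was 0.60 (permutation p = 0.0050). Without chromosomes 3 and X, rho was 0.69 and r was 0.65. Median tags ran only from 21 (chromosome 14) to 26 (chromosome 5). They were 24 on chromosome 15, and 22.5 and 23 on chromosomes 3 and X, which had the fewest sites per gene. Copy number changes ChIP and input alike, so the fold limit would amplify a difference in copy number if the caller holds low inputs at 1, which is undecided. The limit of 2 directional tags per side is a count of ChIP tags, which fewer copies could fail to reach whatever the input. The limit of 17 tags is such a count too, but the fold limit acted first, since an input of 1 needed 19 tags. The fewest tags at any listed site were 19. If the input were held at 1 at every site, 19 tags would pass. Then only 222 of 1343 sites (16.5%) have the 38 tags needed if every count were halved, a 6.05-fold loss. On the same assumption 436 have the 29 tags needed after a drop by 1 part in 3 (3.08-fold loss). The 57 tags needed after a drop to 1 part in 3 are reached by 39 (34.4-fold loss). These drops were picked by hand and pool all chromosomes, and no copy number was measured. A range this wide could hold many ratios, so the 11.2-fold difference per gene lends copy number no support here. The correlation would also follow from stronger or more frequent binding on some chromosomes, which was not tested and stays open. The origin of the chromatin also stays open, given the word Liver in the header. The coverage of the input library along chromosomes, not analysed here, could show unequal copy number. It would not show whether the caller raises low inputs, nor exclude differences in binding.

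Sites lay closer together than random positions. After merging sites within 1 kb, 557 sites still had another within 100 kb, above the highest random set (223). This outcome followed from earlier counts: 636 sites had another within 100 kb, but only 110 had one within 1 kb. Those counts argue against repeated calls within 1 kb as the whole cause, and the merging adds no separate support. Without the 5 windows of 5 Mb with the most sites the number was 551, above the highest random set (198). The size of the windows already implied this outcome. They held 28, 25, 23, 19 and 19 sites, too few to bring 636 down to the highest random set for all sites (237). These window counts argue against those 5 windows as the whole cause, and leaving the windows out adds no separate support. The windows had fixed borders, and the dense stretches named above on chromosomes 1, 2, 10 and 12 stayed in. Dense stretches in general as the cause were therefore not tested. Gene density and the mappability of reads were not tested and stay open.

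The implied input was 1 at 88.1% of sites, but the limit largely sets this share, since sites below 38 tags cannot pass with an input of 2. Among sites with at least 38 tags it was 59.5%, but an input of 3 could pass only from 57 tags. Among the 39 sites with at least 57 tags, 26 (66.7%, exact interval 49.8 to 80.9) had an input of 1. There 3 (7.7%) had an input of 2 and 8 (20.5%) an input of 3. Neither share decides whether the caller raises an input of 0 to 1. Averaged over the mappable genome, 210 bp held 1.84 input tags, so an 18.00-fold limit at this depth may favour places where the input happened to be low. Of the 10 sites with the most tags, the 3 that ranking by fold left out had 3 or 4 input tags. Whether sites with more input tags were lost cannot be told from a list of called sites.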
